A study of Homo sapiens with 6 samples.

How the data were processed

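Gene expression was measured in 5 human cancer cell lines on 6 Agilent 1-colour arrays. Each array read Cy3-marked cRNA made from total RNA of cells grown to near confluence, per the labels' protocols. The line SBC-5 had 2 arrays, called duplicates in the labels, and ACC-LC319/Bone2, NCI-H1048, ZR75.1 and HCC1397 had 1 array each. Groups were taken from the cell line named in the labels, and the name HCC1397 is given as the labels give it.

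The deposited scanner files give a Cy3 intensity per spot, processed with Agilent Feature Extraction 10.7, per the submitters' processing notes. The processed intensity in the deposited files is background-subtracted and detrended within the array, with small values replaced by a positive surrogate, and is not normalized between arrays, per the file headers. The array design was annotated on the genome build hg18, per the file headers. The deposited value table of the series holds log2 values of the same arrays. Setting its columns against the scanner files, over 23747 probes, showed a log2 scale, a slope of 1 between arrays and centring of each probe on the median of the 6 arrays. Its column medians were 0.02 for ACC-LC319/Bone2, 0.43 for NCI-H1048, -0.08 and -0.06 for the SBC-5 arrays, -0.03 for ZR75.1 and 0.04 for HCC1397. The exact shift that the authors applied is not given in the sources used here. The value table was used as an alternative.

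Each array held 45015 spots, of which 43376 were not controls, and 41000 distinct probes. No spot was saturated on any array. The share of spots well above background was 78.5% on ACC-LC319/Bone2, 76.1% on NCI-H1048, 70.1% and 71.5% on the SBC-5 arrays, 71.4% on ZR75.1 and 72.2% on HCC1397. The 75th percentile of the processed intensity was 1560, 1299.7, 1605, 1658, 1405 and 1209 in the same order. Median local background was 18, 42, 22, 22, 22 and 20 intensity units, and the SD of negative controls was 1.97, 4.41, 2.95, 2.44, 2.19 and 1.84, so NCI-H1048 had the brightest background. Of 10 quality metrics of the scanner software, 1 was out of range on ACC-LC319/Bone2, 2 on NCI-H1048, 1 on each SBC-5 array, 1 on ZR75.1 and 0 on HCC1397. The spike-in detection limit was out of range on NCI-H1048 alone, at 2.07. The slide and scan entries of the headers gave 3 slides, each with a scan of its own. ACC-LC319/Bone2 and NCI-H1048 each had a slide of their own, and the 4 arrays of SBC-5, ZR75.1 and HCC1397 shared the other slide. Slide and line therefore cannot be told apart for ACC-LC319/Bone2 and NCI-H1048, and slide could not be a term of the model.

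The main setting was log2 of the processed intensity minus the 75th percentile of the array's spots that are not controls. Spots of one probe were averaged. A probe was kept when it was well above background on every array of at least 1 line, and 51 probes with outlier flags were left out, which left 36565 probes. Probe accessions were matched, without versions, to a RefSeq gene table of the assembly GRCh38.p14. Since that assembly is not the build of the array design, the table was used only for gene names and for which genes neighbour each other. Of 41000 probes, 24794 got 1 gene symbol, 0 got several and 16206 got none. Among 25292 probes with a messenger RNA accession, 24471 matched. Kept probes with a symbol numbered 23306 and covered 16022 genes, and 13259 kept probes had no symbol and entered only an alternative. Where a gene had several kept probes (5631 genes), the probe with the highest mean signal stood for it. Of the 357 pairs of gene and line named by the rule below, 123 had several probes; all probes passed 2-fold in the same direction in 86, and a probe went the other way in 16. A gene was said to be not well above background in a line only where no probe of the gene passed that test there.

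Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in one model with the 5 lines as groups. The 2 SBC-5 arrays give the only residual degree of freedom (1 per gene, with 1.56 prior degrees of freedom from moderation over genes), so each lone array is assumed to vary like them. The labels do not say that the duplicates came from separate cultures, so every p-value measures only the spread between these duplicates, which may be technical. A gene was called in a pair of lines at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 1 on the log2 scale, and called higher or lower in a line when this held against each of the 4 other lines. The median SE of a difference was 0.08 on the log2 scale between lone arrays and 0.07 between SBC-5 and a lone array. The number of arrays limits the precision.

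A probe not well above background has only a bound. Folds against such a line are given as "at least N-fold", from the bright line's mean against, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. The lowest such scaled log2 signal was -6.85 on ACC-LC319/Bone2, -5.21 on NCI-H1048, -6.98 and -7.08 on the SBC-5 arrays, -6.73 on ZR75.1 and -6.72 on HCC1397. The fold of a line call is the one against the nearest other line.

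Genes were named by a rule. Per line, among genes called against each of the other lines, it took the 6 higher genes with the largest margin to the nearest line that were measured on both sides, the 6 higher genes not well above background in any other line with the largest bound, the 4 lower genes measured on both sides, the 4 lower genes not well above background in the line but measured in all others, and up to 4 called members of each of 20 gene lists. This gave 357 distinct pairs of gene and line. Some genes picked by the rule are not named in the text or plotted. The 20 lists (472 entries, 439 distinct genes measured), the test design, the naming rule and the alternative settings named first below were set before the data were examined. For each list and line, the median over members of the line's value minus the mean of the 4 other lines was compared with 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these arrays and is not a p-value. List counts were also taken with p adjusted over the list alone. Most genes past 2-fold also passed the adjusted p over all genes (7527 of 7826 between ACC-LC319/Bone2 and NCI-H1048). Adjusting over the list alone could therefore change few counts, and identical counts are a weak check.

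The model was tested on simulated data with 16022 genes, of which 200 were changed in one line. Of genes changed by 1.5 on the log2 scale, 89% were recovered for ACC-LC319/Bone2, 79% for NCI-H1048, 84% for SBC-5, 81% for ZR75.1 and 83% for HCC1397. At 3 on the log2 scale the shares were 95%, 96%, 99%, 94% and 94%, and wrong calls numbered 5, 2, 1, 0 and 1. All lines were simulated from 1 common mean per gene, with normal noise at the moderated SD and no slide effect. The simulation thus takes for granted that lone arrays vary like the duplicates, and its wrong calls are not the error rate of the real calls. The list and neighbour tests were also tested on simulated data before use.

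These settings were quantile normalization, normexp background correction (offset 50) followed by quantile normalization, the deposited value table, no filter on dim probes, the mean of all probes of a gene, a variance trend with robust moderation, each SBC-5 array left out, and the shared slide alone. Normexp used the median signal of each spot, because the mean signal was not among the columns used here. Alternatives added after seeing the data were dim values set at their bound, probes without a symbol included, the NCI-H1048 array left out, and scaling to the median of the genes tested. Neighbouring genes were compared with 10000 random gene orders. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes of the Y chromosome and XIST are not reported.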

Results

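Expression of 16022 named genes was compared between 5 human cancer cell lines grown to near confluence. NCI-H1048 and SBC-5 are small cell lung cancer lines, ACC-LC319/Bone2 carries the name of the lung adenocarcinoma line ACC-LC319, and ZR75.1 is written like the breast cancer line ZR-75-1. HCC1397 is described in the labels only as a cancer cell line. The labels name no treatment, so each line was set against every other. SBC-5 had 2 arrays and every other line 1, so no value outside SBC-5 has a replicate of its own. Genes well above background numbered 14544 in ACC-LC319/Bone2, 14182 in NCI-H1048, 12837 in SBC-5, 13296 in ZR75.1 and 13320 in HCC1397.

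The SBC-5 duplicates gave the background level of difference. Between them, 357 of 16022 genes (2.23%) were 2-fold apart or more, and 47 of 12837 (0.366%) among genes well above background on both arrays. The median SD per gene was 0.05 on the log2 scale. Across genes, which are not independent replicates, the duplicates had a Pearson correlation of 0.997, against 0.784 (ACC-LC319/Bone2 and NCI-H1048) to 0.845 (ACC-LC319/Bone2 and HCC1397) between different lines.

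Spike-in probes were not used for scaling, and their levels are plotted per array.

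**Figure D1:**
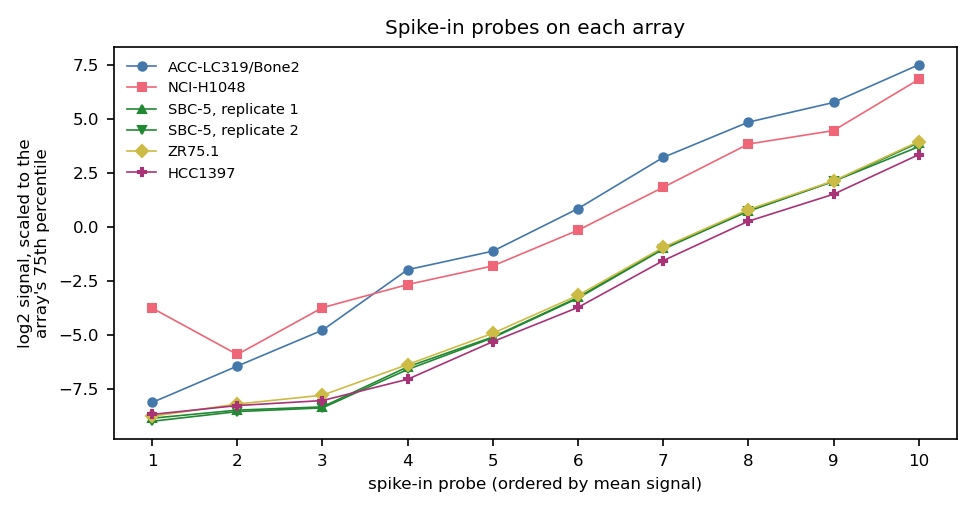
Each line is 1 array and gives the scaled log2 signal of 10 spike-in probes, ordered by mean signal. The arrays of ACC-LC319/Bone2 and NCI-H1048 lie above the 4 arrays of the shared slide at all 10 probes, by a median of 4.10 and 3.15 over the 6 bright ones.

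Every pair of lines differed in many of the genes tested. ACC-LC319/Bone2 differed from NCI-H1048 in 7527 genes, from SBC-5 in 7597, from ZR75.1 in 7894 and from HCC1397 in 7016. NCI-H1048 differed from SBC-5 in 7860 genes, from ZR75.1 in 8113 and from HCC1397 in 7929. Within the shared slide, SBC-5 differed from ZR75.1 in 6870 genes and from HCC1397 in 6812, and ZR75.1 from HCC1397 in 6594. These 3 counts are the within-slide values; the 7 others cross slides. With normexp the 10 counts were lower, from 4452 (NCI-H1048 and SBC-5) to 5470 (ACC-LC319/Bone2 and ZR75.1). The share of calls higher in NCI-H1048 was 69.3% against SBC-5, 64% against ZR75.1 and 65% against HCC1397. It was 51.9%, 51.3% and 52.9% with quantile normalization and 53.8%, 51.7% and 54.3% with normexp. Against ACC-LC319/Bone2, 4292 of 7527 calls were higher in NCI-H1048, but 3784 of 7823 with quantile normalization and 2558 of 5156 with normexp, so the side with more calls changed.

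The number of genes called against each of the 4 other lines is plotted for both scalings. In ACC-LC319/Bone2, 964 genes were higher and 593 lower. NCI-H1048 had 1622 higher and 388 lower, SBC-5 552 and 942, ZR75.1 943 and 938, and HCC1397 642 and 701. With dim values set at their bound, these counts became 782 and 510, 1597 and 341, 527 and 694, 916 and 805, and 624 and 585. With normexp they were 621 and 309, 641 and 291, 443 and 336, 832 and 492, and 557 and 359. Another scaling moved the share of higher calls by over 10 points in 4 lines. It was 80.7% in NCI-H1048, 50.5% with quantile normalization and 68.8% with normexp. In SBC-5 it was 36.9%, then 51.3% and 56.9%. With normexp it went from 50.1% to 62.8% in ZR75.1 and from 47.8% to 60.8% in HCC1397.

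**Figure D2:**
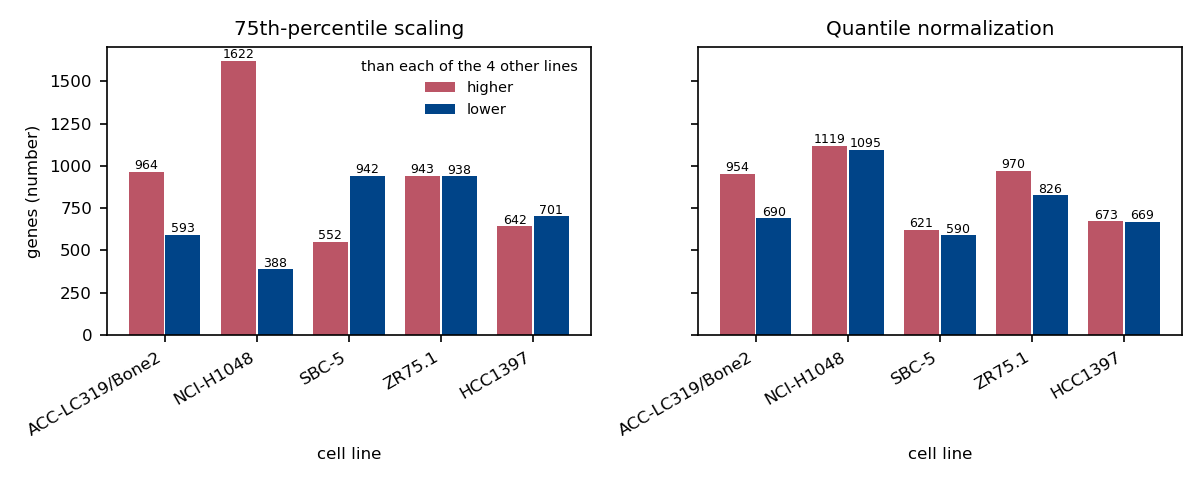
Bars give the number of genes higher or lower in a line than in each of the 4 other lines, with 75th-percentile scaling on the left and quantile normalization on the right. NCI-H1048 had 1622 higher and 388 lower genes on the left, and 1119 and 1095 on the right.

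ZR75.1 had higher levels of many genes of a secretory luminal breast epithelium than any other line, and lower levels of part of the mesenchymal genes. The secretoglobins SCGB2A2 (mammaglobin A), SCGB1D1 and SCGB1D2 were at least 7970-fold, 3820-fold and 3830-fold higher than in any other line, and the trefoil peptide TFF1 was 455-fold higher (log2 difference 8.83 ± 0.10 SE). ADIRF was 1120-fold higher, the luminal transcription factor SPDEF 369-fold, the glycoprotein hormone alpha chain CGA at least 384-fold, the proteoglycan FMOD 436-fold and the gluconeogenic enzyme FBP1 at least 780-fold. TARP, the proteoglycan GPC5 and the cytochrome CYP4B1 were at least 141-fold, 96.1-fold and 74-fold higher and not well above background elsewhere. Lower in ZR75.1 than anywhere else were the glutathione transferase GSTP1 (2840-fold), the intermediate filament VIM (at least 3660-fold), the ubiquitin hydrolase UCHL1 (at least 6310-fold) and the lactate dehydrogenase subunit LDHB (at least 3780-fold). CMTM3 (376-fold), the histone chaperone NPM3 (123-fold), the chromatin remodeller SMARCA1 (123-fold) and the actin-binding TMSB4X (at least 660-fold) were lower too.

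Of 26 measured luminal and oestrogen receptor genes, 13 were higher in ZR75.1 and 1 (STC2) was lower, both over all genes and adjusted over the list alone. Among them were TFF3 (98.4-fold), AGR3 (198-fold) and SPDEF, as well as GATA3 and FOXA1 at scaled log2 levels of 2.46 and 5.45. The probe that stood for the oestrogen receptor gene ESR1 was well above background in every line but NCI-H1048, with close levels (-3.82 in ZR75.1, -4.06 in SBC-5), and gave no call. Another ESR1 probe was well above background in ZR75.1 alone (-4.37), so its probes disagree. The other 12 members had no call. Among them GREB1 was lowest in ZR75.1 (-6.3 against -3.3 in HCC1397). The probe that stood for PGR was not well above background in ZR75.1 (-6.9) but was in ACC-LC319/Bone2 (-3.4). STC2, GATA3, FOXA1, ESR1, GREB1 and PGR were chosen after their values were seen. Epithelial adhesion genes were higher in 10 of 22 (17 without the NCI-H1048 array), with E-cadherin (CDH1) 34.5-fold, the splicing factor ESRP2 20.8-fold and the claudin CLDN4 13.9-fold above the nearest line. Cholesterol synthesis genes were higher in 7 of 22, with MSMO1 4.8-fold and TM7SF2 3.73-fold. Of 24 p53 targets, 4 were higher, led by CDKN1A (5.5-fold) and PHLDA3 (3.3-fold). Mesenchymal genes were lower in 7 of 24 and interferon response genes in 7 of 26, with 1 interferon gene higher (0 without SBC-5 replicate 2); HERC5 was at least 51.9-fold and ISG15 4.61-fold lower. With dim values at their bound 4 mesenchymal and 5 interferon genes were lower, and with normexp 4 and 3. Of the mesenchymal genes 11 were well above background in ZR75.1. The counts of these 5 lists adjusted over the list alone were identical. ERBB2, a receptor tyrosine kinase, was 6.73-fold higher.

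SE values of these differences come from the duplicates of another line, and the largest adjusted p (limma) among the 20 leading genes of ZR75.1 was 0.00843, for CYP4B1. The secretoglobins SCGB1D1 and SCGB1D2 and TMSB4X have close relatives, and TARP overlaps a T cell receptor gene, so which transcript was measured is uncertain.

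HCC1397 combined a mesenchymal matrix programme, interferon-response transcripts and basal keratins. The chemokine CXCL12 was 911-fold higher than in the nearest line, the matrix protein SPARC 878-fold (9.78 ± 0.27 SE), the collagen COL8A1 695-fold and the transcription factor TWIST2 at least 215-fold. The collagen chain COL1A2, the hyaluronan-binding TNFAIP6, the cadherin CDH11, the BMP antagonist GREM1, BRINP1 and the chemokine CCL11 were not well above background in any other line, and were at least 745-fold, 379-fold, 371-fold, 115-fold, 58.4-fold and 47.2-fold higher. SCRG1 (423-fold) and the hyaluronidase CEMIP (306-fold) were also higher. The actin-nucleating subunit ACTR3 was not well above background in HCC1397 on any of its 3 probes and at least 1070-fold lower than elsewhere. ARMCX5, SNURF and the peroxisomal enzyme HSD17B4 were at least 205-fold, 191-fold and 168-fold lower. SCRN1 (242-fold), GCHFR (91.1-fold), the epithelial adaptor AP1M2 (78.4-fold) and the desmosomal protein DSP (69.5-fold) were lower as well.

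Of 26 interferon response genes, 18 were higher in HCC1397 and 0 lower, with IFI6 62.2-fold, IFIT1 57.4-fold, OAS2 40.8-fold and OASL 32.1-fold above the nearest line. Mesenchymal genes were higher in 11 of 24, COL5A1 by 84.1-fold and fibrillin FBN1 by 23.4-fold. Basal epithelial genes were higher in 5 of 20, with the keratin KRT5 28.8-fold and KRT6B 7.82-fold, and in 8 without the NCI-H1048 array. Of 25 bone metastasis genes, 8 were higher, among them the decoy receptor TNFRSF11B (28.4-fold), RUNX2 (17.1-fold) and VEGFA (9.84-fold). Antigen presentation genes were higher in 6 of 23, including B2M (3.91-fold), HLA-B (3.34-fold) and HLA-F (3.25-fold). Hypoxia and glycolysis genes were higher in 3 of 24, and of 19 cancer-testis antigens 4 were lower. With normexp 3 antigen presentation genes were higher and 1 cancer-testis antigen lower. The counts of these 7 lists adjusted over the list alone were identical.

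The largest adjusted p among the 20 leading genes of HCC1397 was 0.00762, for CCL11. KRT6B, OAS2, the IFIT genes and the HLA genes have near-identical relatives, and SNURF overlaps SNRPN, so their values are uncertain.

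NCI-H1048 had higher levels of several tuft cell genes than any other line. The lipoxygenase ALOX5 and the receptor tyrosine kinase KIT were not well above background in any other line and at least 2790-fold and 929-fold higher, IRAG2 was 1060-fold higher (10.04 ± 0.18 SE) and POU2F3, the transcription factor that specifies tuft cells, 143-fold. Cartilage collagen COL2A1 (at least 2280-fold), the lipoprotein lipase LPL (at least 483-fold), the keratin KRT1 (at least 398-fold) and the protease inhibitor SPINK6 (at least 234-fold) were likewise not well above background elsewhere. KRT7 (281-fold), the axonemal protein DNALI1 (204-fold), SPMIP5 (176-fold) and the secreted WFDC2 (159-fold) were higher. TMCO1 (at least 121-fold), the kinase STK26 (at least 83.1-fold) and CEP15 (at least 44.2-fold) were not well above background in NCI-H1048 and lower than in any other line. The phosphatase DUSP23 (204-fold), ALDH7A1 (82.7-fold), OPLAH (53.9-fold) and the cytokine receptor TNFRSF12A (37.1-fold) were also lower.

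Of 19 measured tuft cell genes, 9 were higher in NCI-H1048 and 0 lower over all genes, and 10 were higher adjusted over the list alone. Among those with no call were TRPM5 and ASCL2, at -3.25 and 2.15 in NCI-H1048 against -2.26 in ACC-LC319/Bone2 and 2.42 in ZR75.1. Basal epithelial genes were higher in 3 of 20, led by the keratin KRT15 (38.2-fold), and neuroendocrine genes in 3 of 24, led by ISL1 (28.9-fold), with identical counts adjusted over the list alone. Over all genes 1622 of 16022 were higher, so the neuroendocrine count lay near that share. The median of the neuroendocrine list lay at percentile 49.4 of the random lists. NEUROD1, a transcription factor of neuroendocrine cells, was not well above background in NCI-H1048. TRPM5, ASCL2 and NEUROD1 were chosen after their values were seen. Growth control and receptor oncogenes were higher in 5 of 29 (6 adjusted over the list alone), and the tumour suppressor RB1 was 10.1-fold lower. With normexp 3 of these and 0 endothelial and erythroid markers were higher, and with the mean of probes 5 basal epithelial and 5 neuroendocrine genes. Of 22 epithelial adhesion genes 0 were called by limma against every other line, although the median of the list lay 2.84 above that of all genes. Of 13 endothelial and erythroid markers 3 were higher and 1 lower (ALAS2, not well above background on the probe that stood for it, and 0 lower with dim values at their bound), and of 16 leukocyte markers 1 (PTPRC) was higher, and the higher ones lay at scaled log2 levels of -4.03 or less, where the lowest signal well above background on that array was -5.21. Of the 1622 higher genes, 1356 lay in the dimmest of 3 equal groups of genes by mean signal.

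The largest adjusted p among the 20 leading genes of NCI-H1048 was 0.00341, for POU2F3. Its array had the brightest background of the 6, and slide and line cannot be told apart for it.

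SBC-5 had higher levels of several cancer-testis genes than any other line, and lower levels of some basal epithelial and epithelial adhesion genes. CT45A5 was 1380-fold higher than in the nearest line (10.43 ± 0.06 SE), FAM9C 525-fold, the homeobox gene HOXB2 327-fold and the meiotic gene MEIOB 150-fold. MAGEA9, the pentraxin NPTX2, PASD1, NUDT10, the CTCF paralogue CTCFL and the neuronal STMN2 were not well above background in any other line and at least 957-fold, 147-fold, 125-fold, 114-fold, 71.5-fold and 57-fold higher. The transcript SOX2-OT (at least 77.8-fold) and the receptor NPFFR2 (at least 65.2-fold) were higher. OCIAD2 was not well above background in SBC-5 and at least 2110-fold lower than elsewhere. The ketone body enzyme OXCT1 (at least 345-fold), the thioredoxin-binding TXNIP (at least 240-fold) and S100A10 (at least 238-fold) were likewise lower. The syndecan SDC4 (124-fold), the peptidase DPP7 (93.9-fold), the myosin MYO10 (92-fold) and the desmosome-associated PERP (84.3-fold) were lower but measured.

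Of 19 cancer-testis antigens, 8 were higher in SBC-5 and 0 lower, with CT45A1 at least 1680-fold, the helicase DDX43 79.3-fold, MAGEA1 36-fold and MAGEA4 30.5-fold. Their mean difference was 2.62, but their median went the other way (-0.31 relative to all genes), and it was 0.72 with quantile normalization, 0.07 with normexp and 0.57 without the NCI-H1048 array. Cell division genes were higher in 3 of 25, and in 6 without the NCI-H1048 array (RRM2 3.05-fold, MCM6 2.79-fold, BUB1 2.01-fold). Basal epithelial genes were lower in 8 of 20, NRF2 targets in 7 of 23, epithelial adhesion genes in 5 of 22 and p53 targets in 5 of 24, where the median (0.07) and the mean (-0.76) differed in sign. These 4 counts became 5, 5, 3 and 4 with quantile normalization and 3, 3, 2 and 3 with normexp, and with dim values at their bound 4 NRF2 targets were lower. Examples were the laminin LAMB3 (46.3-fold), AKR1C1 (6.33-fold), MAL2 (at least 32.5-fold) and CDKN1A (5.38-fold). YAP and TEAD targets were lower in 4 of 21 and higher in 1, CCN2 by 11.4-fold. Neuroendocrine genes were higher in 4 of 24 and lower in 1 (2 without SBC-5 replicate 2), ENO2 by 11.4-fold. With normexp 2 YAP and TEAD targets were lower and 1 neuroendocrine gene higher, and with the mean of probes 2 neuroendocrine genes were higher. The counts of these 8 lists adjusted over the list alone were identical.

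The largest adjusted p among the 20 leading genes of SBC-5 was 0.00104, for MYO10. CT45A1 and CT45A5, the MAGEA genes and NUDT10 have near-identical copies, so which copy was measured is uncertain.

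ACC-LC319/Bone2 had higher SPANX genes and some higher NRF2 targets than any other line, and B2M was not well above background. SPANXA1 and SPANXD, expressed in sperm, were 1960-fold (10.93 ± 0.06 SE) and 1220-fold higher than in the nearest line, the hexokinase-like HKDC1 732-fold, the protease PRSS21 288-fold and the carboxylesterase CES1 180-fold. B3GAT1 was at least 102-fold higher. PGAP4, LXN, the transcription factor ZFP42, the transporter SLCO2B1, the butyrylcholinesterase BCHE and G0S2 were not well above background in other lines and at least 235-fold, 196-fold, 182-fold, 163-fold, 151-fold and 131-fold higher. B2M, the light chain of class I antigen-presenting molecules, was not well above background and at least 1250-fold lower than in any other line. TSTD1 (at least 377-fold), KLHL9 (at least 366-fold) and DMKN (at least 258-fold) were lower too. PNPLA4 (219-fold), the kinase PRKCZ (117-fold) and the paralogues TCEAL5 (106-fold) and TCEAL6 (103-fold) were lower but measured.

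NRF2 targets, genes of the oxidative stress response, were higher in 6 of 23, with the ferritin light chain FTL 6.13-fold, SRXN1 4.4-fold, ME1 3.63-fold and GCLC 3.07-fold. HCC1397 had a list median close to that of ACC-LC319/Bone2 (2.01 against 2.39 relative to all genes), and higher AKR1C1 (7.30 against 6.42) and AKR1C3 (7.03 against 6.82), chosen after their values were seen. YAP and TEAD targets were higher in 4 of 21, 5 adjusted over the list alone, with ANKRD1 at least 26.2-fold and AMOTL2 4.06-fold, and DLC1 was 31.2-fold lower. In HCC1397 4 of these targets were higher too and 0 lower. The mean difference of the list was 1.61 there, against 1.66 in ACC-LC319/Bone2. Its median relative to all genes was 0.83 against 1.52. Growth control and receptor oncogenes were lower in 4 of 29, among them CCNE1 (3.74-fold), and MYC was 3.84-fold higher. With normexp 1 gene of that list was lower. Mesenchymal genes were higher in 2 of 24, S100A4 by 13.9-fold, and lower in 1. Bone metastasis genes were higher in 2 of 25 (SPP1 12.8-fold, VCAM1 3.25-fold) and lower in 2 (IL11 3.05-fold, TNFRSF11A 2.27-fold). Of 24 p53 targets 3 were higher, GDF15 by 3.42 on the log2 scale, and 1 was lower. Of 17 lung epithelial genes 1 was higher, FOXA2 by 5.48-fold. Over all genes 964 of 16022 were higher, so the mesenchymal, bone metastasis and lung epithelial counts of higher genes lay near that share. The list medians lay at percentile 100 for mesenchymal, 87.0 for bone metastasis, 49.2 for p53 target and 47.5 for lung epithelial genes. Without the NCI-H1048 array, 4 bone metastasis, 3 lung epithelial and 3 growth control genes were higher, and 2 p53 targets lower. Except where given, counts adjusted over the list alone were identical.

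The largest adjusted p among the 20 leading genes of ACC-LC319/Bone2 was 0.00722, for SLCO2B1. SPANXA1, SPANXD and the TCEAL genes have near-identical relatives, FTL has processed copies, and slide and line cannot be told apart for this array.

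**Figure D3:**
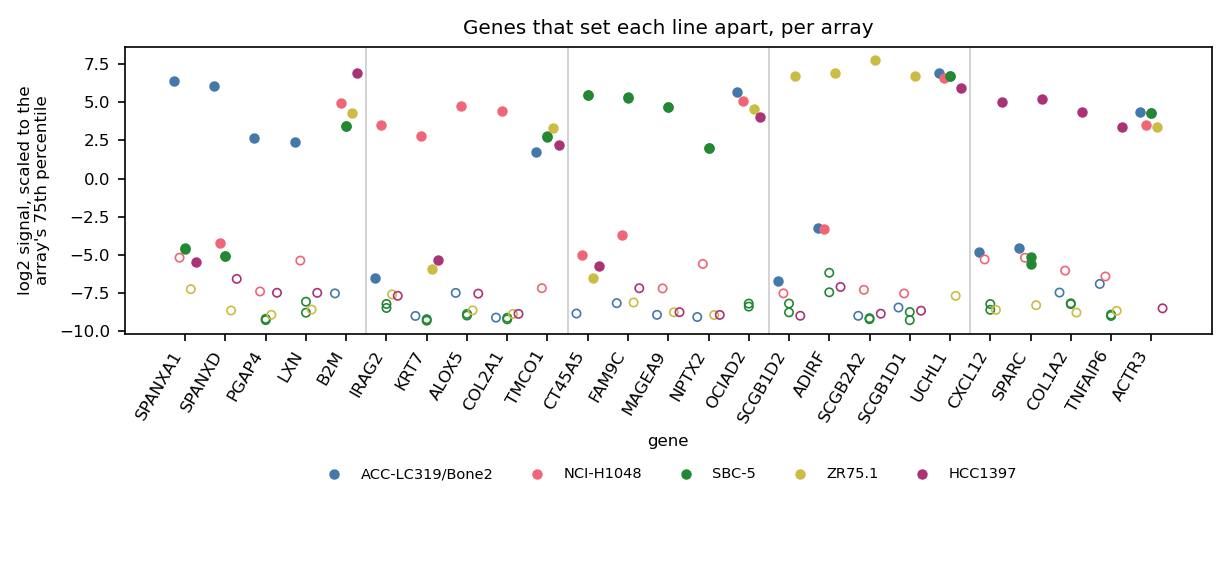
Each point is the log2 signal of a gene on 1 array, scaled to the array's 75th percentile; filled points are well above background and open points are not. Colours are the lines (SBC-5 has 2 arrays), and grey lines part blocks of 5 genes for ACC-LC319/Bone2, NCI-H1048, SBC-5, ZR75.1 and HCC1397, the last gene of each block being lower in that line, such as B2M at -7.52 in ACC-LC319/Bone2.

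List medians were set against the shift of all genes, which was 0.08 in ACC-LC319/Bone2, 0.25 in NCI-H1048, -0.21 in SBC-5, -0.14 in ZR75.1 and -0.19 in HCC1397 on the log2 scale. With quantile normalization these shifts were 0.05, 0.03, -0.02, -0.02 and -0.11. Relative to them, tuft cell genes lay 5.00 higher in NCI-H1048, and luminal genes 4.28 higher and epithelial adhesion genes 5.10 higher in ZR75.1, each at percentile 100 of the random lists. In HCC1397 the median was 5.09 for mesenchymal genes, 3.89 for interferon response, 2.30 for basal epithelial genes and 1.92 for antigen presentation, each at percentile 100. The basal epithelial median was nearly as high in NCI-H1048 (2.13, percentile 100). NRF2 targets lay at 2.39 in ACC-LC319/Bone2, 2.01 in HCC1397 and -2.22 in NCI-H1048. In SBC-5 the median was -4.26 for epithelial adhesion, -3.06 for basal epithelial genes and 1.13 for cell division. In ZR75.1 mesenchymal genes lay at -4.12, interferon response at -2.67 and cholesterol synthesis at 1.18. Interferon response genes were low in SBC-5 too (-1.92).

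Within the shared slide, against the 2 other lines there, the medians given next had the same sign as over all slides. They were 4.97 for luminal, 8.39 for epithelial adhesion, -3.80 for mesenchymal, -2.52 for interferon response and 0.85 for cholesterol synthesis genes in ZR75.1. In HCC1397 they were 7.21 for mesenchymal, 4.65 for interferon response, 2.94 for basal epithelial, 2.61 for antigen presentation and 1.51 for NRF2 targets. In SBC-5 they were -4.50 for epithelial adhesion, -2.63 for basal epithelial, -2.95 for interferon response and 1.15 for cell division genes. The cancer-testis median in SBC-5 was 1.75 within the slide but below 0 over all slides. Other lists changed sign too. Tuft cell genes went from -1.20 to 0.42 in ZR75.1 and from -1.21 to 0.29 in HCC1397, and p53 targets from 0.07 to -0.15 in SBC-5. In at least 1 line the neuroendocrine, lung epithelial, hypoxia and glycolysis, cholesterol synthesis, growth control, leukocyte, and endothelial and erythroid lists did so as well. Quantile normalization or normexp changed the sign of the median, relative to all genes, in at least 1 line for the neuroendocrine, lung epithelial, hypoxia and glycolysis, p53 target, growth control, leukocyte, and endothelial and erythroid lists. The same held for the cancer-testis list in SBC-5, the luminal and oestrogen receptor list in NCI-H1048, the bone metastasis list in ACC-LC319/Bone2 and the cholesterol synthesis list in HCC1397.

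**Figure D4:**
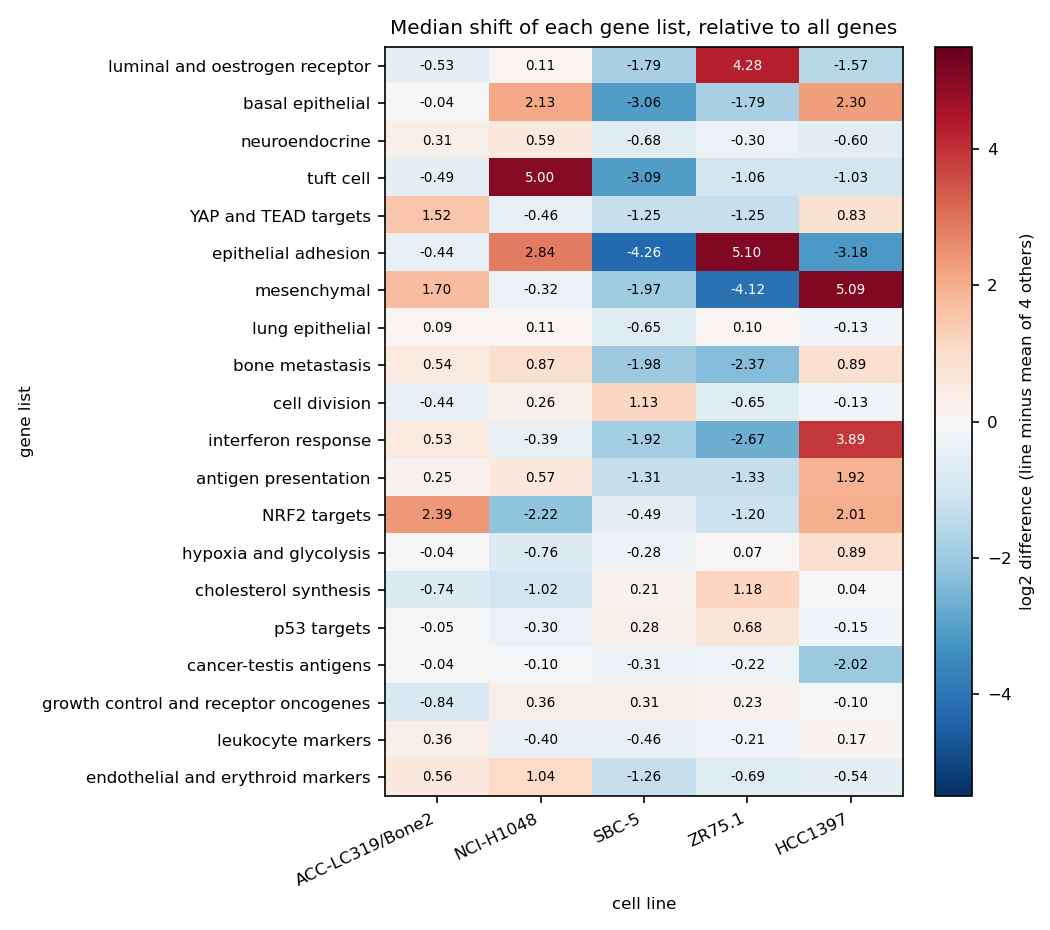
Colour and number give the median log2 difference of each gene list in a line against the mean of the 4 other lines, minus the same median of all genes. The largest values are 5.10 for epithelial adhesion in ZR75.1, 5.09 for mesenchymal genes in HCC1397 and 5.00 for tuft cell genes in NCI-H1048, while values near 0, and the 1.04 of endothelial and erythroid markers in NCI-H1048, can change sign with the scaling.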

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

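The tests of the spike-in probes, of the slide and scan of the NCI-H1048 array, of fibroblasts and of a slide effect in HCC1397 were chosen after the results were seen, and so was scaling to the median as an alternative.

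The spike-in probes, which read RNA added in the laboratory and enter no comparison, were brighter on the arrays of ACC-LC319/Bone2 and NCI-H1048 than on the 4 arrays of the shared slide. Over the 6 spike-in probes bright on every array, the median offset from the shared slide was 4.10 on the log2 scale (17.2-fold) for ACC-LC319/Bone2 and 3.15 (8.88-fold) for NCI-H1048. All 10 spike-in probes lay above every array of the shared slide on both. The arrays of the shared slide differed from each other by 0.16, 0.11, 0.25 and -0.50. A brighter scan or stain of the whole array is argued against, because the unscaled 75th percentile of sample probes differed from the shared slide by at most 0.17. A different amount of spike-in RNA relative to sample RNA may be the source: the offsets of the 6 bright probes stayed within a range of 0.82. No biological explanation was tested, since the spike-in RNA does not come from the cells. Gene comparisons were scaled without the spike-ins.

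NCI-H1048 had 1622 higher and 388 lower genes. A scaling constant that sets the whole array too high is argued against: with each array scaled to the median of the genes tested, 74.2% of its calls were still higher, against a bound of 65% set before that test. Quantile normalization, tried first, gave 50.5%, and normexp followed by it 68.8%. Both change more than a constant per array, so neither tests a constant alone, and why they differ from median scaling was not tested. Dim signals raised on an array with a brighter background stay open. In the dimmest of 3 equal groups of genes 1356 calls were higher and 42 lower (97% higher), while in the brightest group 60 were higher and 193 lower (23.7%), a share that fell outside both ranges set for the test. The slide and scan of this array cannot be told apart from the line, because 0 arrays of another line lay on that slide. A difference between the cell lines themselves also stays open and was not tested. The excess could come from any of these, and the share of higher calls in NCI-H1048 is not a measure of the line alone.

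HCC1397 had higher matrix and mesenchymal genes, COL1A2 and SPARC among them. A list of fibroblast markers, set before the test, was used to look for fibroblasts mixed into the culture. The level of 1 of them, COL3A1, had been seen by then. Of 18 measured markers 15 were well above background in HCC1397, but 5 were higher than in each other line, under the bound set for the test. That count also depends on the markers' levels in the other lines, so it cannot decide the question and fibroblasts stay open. FBLN1 lay at 4.16 in NCI-H1048 and 1.70 in HCC1397, and PDGFRA at 1.36 in SBC-5 and -0.55 in HCC1397. COL3A1, an abundant fibroblast transcript, lay at -6.14 in HCC1397, LUM was not well above background and CTSK lay at -2.03, lower than in each other line. A slide effect is argued against, because the mesenchymal medians of the other lines on that slide were -4.26 in ZR75.1 and -2.18 in SBC-5. Both met the bound of below 0, but that bound alone is weak, since each median is taken against lines that include HCC1397. They also lay below ACC-LC319/Bone2 (1.77) and NCI-H1048 (-0.07), which have slides of their own. With a slide effect argued against, fibroblasts or a mesenchymal state of the line itself may be the source. The second is a hypothesis found on this array and was not tested.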

How the results depend on the processing

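Alternatives with dim values at their bound, probes without a symbol, the NCI-H1048 array left out and median scaling were chosen after seeing the data. No paired analysis was possible because only SBC-5 has replicates.

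All 21 counts stayed within 1.5 times their value with the deposited value table, without a filter on dim probes and with the mean of all probes. All 20 counts computed did so with a variance trend, median scaling and without either SBC-5 array (with no test there, calls were made by size), and 10 of 10 with dim values at their bound. Without an SBC-5 replicate, lower genes in SBC-5 numbered 1056 to 1151. No gene called in a line was called in the opposite direction under any alternative compared (0 in each).

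With normexp, genes differing fell to 4559 between ACC-LC319/Bone2 and SBC-5, 4650 between ACC-LC319/Bone2 and HCC1397, and 4452, 5216 and 5174 between NCI-H1048 and SBC-5, ZR75.1 and HCC1397. Line calls became 621 higher and 309 lower in ACC-LC319/Bone2, 641 higher in NCI-H1048, and 336, 492 and 359 lower in SBC-5, ZR75.1 and HCC1397. The duplicates had 32 genes 2-fold apart. The added offset shrinks differences of dim genes by its construction. Quantile normalization gave 1095 lower genes in NCI-H1048 (354 of the 388 shared) and 590 in SBC-5; the cause was not tested.

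With only the shared slide, higher and lower genes numbered 1673 and 1703 in SBC-5, 1950 and 1527 in ZR75.1 and 1821 and 1383 in HCC1397, since a call then has to hold against fewer lines. Without the NCI-H1048 array, 1730 genes were higher in ACC-LC319/Bone2 and 939 in SBC-5, for the same reason. With probes without a symbol included, more features were tested. Features differing from ACC-LC319/Bone2 numbered 14123 (NCI-H1048), 13802 (SBC-5), 14024 (ZR75.1) and 12698 (HCC1397). From NCI-H1048 they numbered 14740 (SBC-5), 14774 (ZR75.1) and 14395 (HCC1397). The remaining pairs had 11442 (SBC-5 and ZR75.1), 11126 (SBC-5 and HCC1397) and 11025 (ZR75.1 and HCC1397). Higher and lower features were 1726 and 1495 in ACC-LC319/Bone2, 3600 and 613 in NCI-H1048, 981 and 1442 in SBC-5, 1465 and 1584 in ZR75.1, and 972 and 1138 in HCC1397.

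Of the 357 named pairs of gene and line, the call was lost with its direction kept in 24 with quantile normalization, 71 with normexp, 4 with the value table, 16 with the mean of probes, 8 with a variance trend and 7 with median scaling, and in 0 without a dim filter. Margins reversed for CIITA in NCI-H1048 (-0.37 with quantile normalization, -0.03 with normexp), ME1 in SBC-5 (0.58, 0.15), CBR1 in ZR75.1 (0.53, 0.16), SLC2A3 in ZR75.1 (0.16, 0.16) and SPANXA1 in ZR75.1 (0.04, 0.06). With the mean of probes they reversed for CDKN2B (0.29) and ALAS2 (-0.20) in ACC-LC319/Bone2 and ALAS2 in NCI-H1048 (1.44). The leukocyte list in NCI-H1048 moved from -0.15 to 0.17 without a dim filter. The cause of these reversals was not tested. Signal over background limits the dim genes, for which only bounds are given.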

Other observations

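The tests of neighbouring genes were set before their results were seen; MTAP, CDKN2A and CDKN2B were chosen after their values were seen.

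MTAP, a neighbour of CDKN2A on the chromosome, was not well above background on any of its 3 probes in ACC-LC319/Bone2 (-8.88) and HCC1397 (-8.32), and lay at -0.41, -0.56 and -1.19 in NCI-H1048, SBC-5 and ZR75.1. CDKN2A itself was well above background in both lines, at -1.44 in ACC-LC319/Bone2 and -2.58 in HCC1397. The probe that stood for CDKN2B, beside CDKN2A, was not well above background in either (-8.98 and -7.54). With the mean of the CDKN2B probes the margin in ACC-LC319/Bone2 reversed, so these probes disagree. DNA was not measured.

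The next test took genes not well above background in one line, measured in all others and called lower than in each of them. They may lie next to each other because neighbours are lost together, by deletion or by silencing. They numbered 90 in ACC-LC319/Bone2, 77 in NCI-H1048, 245 in SBC-5, 214 in ZR75.1 and 154 in HCC1397. Over 15991 ordered genes, HCC1397 had 10 adjacent pairs of such genes, against a mean of 1.49 in 10000 random orders (permutation p 0.0001, the smallest these orders can give, adjusted p 0.0005). SBC-5 had 10 against 3.73 (p 0.0049, adjusted 0.0092) and NCI-H1048 3 against 0.37 (p 0.0055, adjusted 0.0092). ACC-LC319/Bone2 had 2 against 0.50 (p 0.086, adjusted 0.11) and ZR75.1 4 against 2.84 (p 0.32, adjusted 0.32), so neither passed. The pairs included SLC35F5 and ACTR3, and DIAPH3 and TDRD3, in HCC1397, and ANKRD22, STAMBPL1 and ACTA2 in SBC-5. SNRPN and SNURF in HCC1397 overlap, so that pair is not independent. The random orders ran over all ordered genes, also those not measured in all other lines, which could not be such genes. If genes measured in all lines tend to lie together, the random means are too low, which was not tested. These p-values therefore do not decide whether neighbours were lost together. Deletion and silencing cannot be separated by expression.

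Genes higher in one line with dim values at their bound also lay next to each other in all 5 lines. They may be gained together, by amplification or by shared regulation. Adjacent pairs numbered 80 against a random mean of 37.9 in ACC-LC319/Bone2, 257 against 156 in NCI-H1048, 77 against 17 in SBC-5, 111 against 52.2 in ZR75.1 and 77 against 24.3 in HCC1397, each at a permutation p of 0.0001, the smallest these orders can give. The runs in ZR75.1 included KDM2A, GRK2, ANKRD13D, SSH3 and POLD4, and TFF3, TFF2 and TFF1. SBC-5 had HOXB2 to HOXB6, HCC1397 had OAS1, OAS3 and OAS2, and NCI-H1048 had FCRL4, FCRL3, FCRL2 and FCRL1. Gene families with shared regulation or sequence form part of these runs. The random orders were not matched on signal. In NCI-H1048, 1356 of the 1622 higher genes lay in the dimmest of 3 equal groups, on the array with the brightest background. Raised dim signals of neighbouring genes could give such pairs too, so they cannot be told apart from gain in that line.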
